A study of Mus musculus with 2 samples.

How the data were processed

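H3K27ac was measured by chromatin immunoprecipitation and sequencing in whole heart tissue of mouse embryos at day 16.5, in 2 biological replicates of 1 group. The replicate numbers are those of the labels. Per the labels, the material was pooled from both sexes, and that of replicate 2 came from 41 embryos. The deposited files used here were peak lists in narrowPeak format on mm10, 1 per replicate, 1 from both replicates pooled and 1 of replicated peaks. Per the file headers that accompany the samples, each replicate's list was derived from that replicate's own alignments and further files whose role is not stated, 2 files for replicate 1 and 1 file for replicate 2. The pooled list was derived from the alignments of both replicates, and the replicated list from the 3 other lists. The aligner, the peak caller and its threshold are not given in the sources used here.

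The signal value of each peak is the authors' own, and its definition is not given in the sources used here. It was used to describe, rank, filter and weight peaks within a list, for the rank correlation between replicates over matched peaks, and as the mean of both replicates to rank genes and compare gene groups. Its scale is not known to be comparable between lists. Where the plan named fold enrichment this signal value was taken. The deposited −log10 p and −log10 q of each peak are also the authors' values. The smallest deposited −log10 p was 2.00, and 2.96% of replicate 1 peaks, 10.4% of replicate 2 peaks and 2.63% of replicated peaks had a q above 0.05. No read counts or library totals were in the lists, so the depth of each sample is unknown, and a library sequenced more deeply can give more weak peaks. Median −log10 p was 7.00 in replicate 1 and 5.86 in replicate 2. Intervals on shares of peaks cover counting error only.

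Genes were the 21938 protein-coding genes of the GENCODE annotation supplied for this build, with 93513 transcript starts, and sequence came from the reference genome of the same build. No peak ran past the end of its chromosome. Peaks on unplaced or unlocalised sequences were left out of the comparisons between the replicates' lists and of those with genes and motifs. They were kept in the descriptions of whole lists and in the comparison of the replicated list with the other lists. A peak was shared when at least 50% of it was covered by peaks of the other replicate. Chance levels came from 20 shuffles of positions within chromosomes. A promoter peak overlapped the 1 kb on either side of any annotated transcript start of a gene, and the strongest such peak, taken in each list separately, gave the gene's signal value, so a gene's values in the replicates can come from different peaks. Remaining peaks were placed by their summit in untranslated regions, other exons, introns or between genes. Distal peaks lay over 2.5 kb from every coding start.

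The gene lists and tests of the report, most alternatives and the rule for naming genes were fixed before the data were examined. The further lists, alternatives and tests chosen afterwards are named in the closing section. There were 19 lists with 363 members, of which 1 symbol was absent from the coding annotation and 1 gene stood in 2 lists. Promoter counts per list were compared with all other coding genes by Fisher's exact test. Distal coverage was the length of peaks from 2.5 to 50 kb on either side of a start, without the promoter windows of coding genes, and a list's median was compared with 10000 random lists matched on gene density by a permutation test. Distal peaks within 12.5 kb were joined into domains and ranked by the sum of width times signal value. With both axes scaled to 1, the point of slope 1 separated the top domains, and each domain was assigned to the coding gene with the nearest start, without any measurement of contact. Fisher's exact test compared list members nearest to a top domain with other genes nearest to any domain. Consensus motifs were counted on both strands in 500 bp windows at distal summits and in as many windows matched on GC content outside pooled peaks. Tests were two-sided with Benjamini-Hochberg adjustment over the 19 lists or 12 motifs, and a result passed at an adjusted p under 0.05. Genes and windows, not samples, are the units of these tests, so their p-values describe these 2 libraries only.

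Genes were named by rule: in each list the 4 members with the highest mean promoter signal value of both replicates and up to 3 members with no promoter peak in either, the genes nearest to the first 15 domains, the 10 genes with the highest promoter signal value, and 10 cardiac genes always named. Not every gene the rule takes is described. Alternatives covered the overlap rule, the p threshold, list length, promoter window, CpG-matched random lists, distal window and measure, joining distance, promoter peaks within domains, motif window and background, and each replicate left out, which leaves the peaks of the other replicate alone. Promoter CpG content was taken within 500 bp of a gene's most upstream start, whereas its promoter peak could lie at any start. The CpG-matched lists were not matched on the number of starts per gene. In simulations of the promoter test, 4% of 300 random lists passed, and 100% of 300 lists with 19 of 20 members marked. In simulations of the distal test, 4.5% of 200 random lists passed, and 98.5% of 200 lists raised 4 times. Lists with lowered values were not simulated. Overlaps were checked against bedtools 2.31.1. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.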

Results

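Hearts of mouse embryos at day 16.5 were profiled by chromatin immunoprecipitation and sequencing for histone H3 acetylated at lysine 27 (H3K27ac), a mark carried by active promoters and enhancers. The samples form 1 group of 2 biological replicates, each from pooled hearts of both sexes of the B6NCrl strain. Replicate 2 came from 41 embryos, and the number behind replicate 1 is not stated. No second condition, stage or tissue was analysed here, so the data allow a description of where the mark lay and a comparison between the replicates. There were 4 peak lists, 1 per replicate, 1 from both replicates pooled and 1 of replicated peaks. The lists hold no read counts, so the sequencing depth is unknown.

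The replicates shared most of their strong peaks and few of the weak peaks of replicate 1. Of the strongest 10% of replicate 1 peaks, 99.6% were at least 50% covered by replicate 2 peaks, against 16.7% of the weakest 10%. For replicate 2 the same shares ran from 100% to 48.3%. Replicate 1 had 101897 peaks over 60.8 Mb and replicate 2 had 77902 peaks over 46.9 Mb, with median widths of 346 and 375 bp. On the main chromosomes, 51831 of 101890 replicate 1 peaks (50.9%, Wilson 95% interval 50.6 to 51.2) and 61511 of 77897 replicate 2 peaks (79.0%, 78.7 to 79.2) were shared by this measure. Peaks shuffled within chromosomes gave 1.82% and 2.36% (means of 20 shuffles). The lists had 40.2 Mb in common out of 67.5 Mb covered by either, a Jaccard index of 59.5%. Across 55771 pooled peaks matched in both replicates, the signal values had a Spearman correlation of 0.765. This correlation is across regions, which are not independent replicates, and no p-value was computed.

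**Figure D1:**
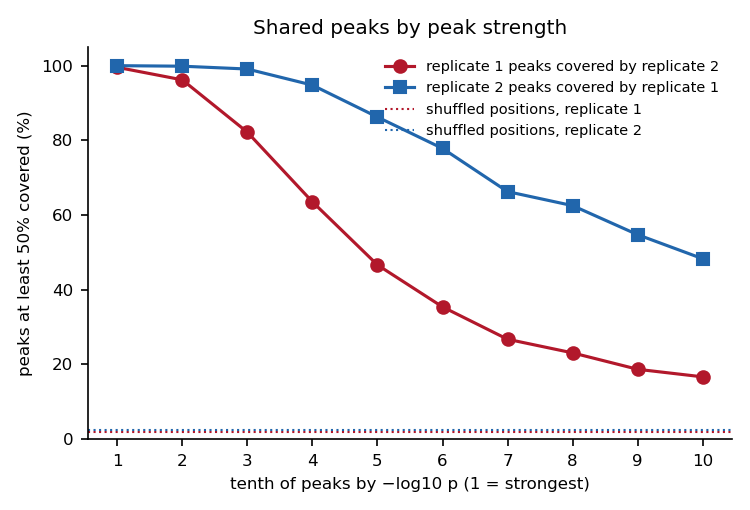
Share of peaks at least 50% covered by peaks of the other replicate (y axis, %) in 10 equal groups of peaks ranked on −log10 p (x axis, 1 is the strongest), with red circles for replicate 1, blue squares for replicate 2 and dotted lines for shuffled positions. Both curves start near 100% and fall to 16.7% for replicate 1 and 48.3% for replicate 2, above the shuffled levels of 1.82% and 2.36%.

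The authors' replicated list held 74952 peaks over 57.5 Mb, a length equal to 2.11% of the main chromosomes, with a median width of 491 bp. Each of its peaks was identical to a pooled peak, so 87.5% of the 85623 pooled peaks were kept (Wilson 95% interval 87.3 to 87.8). At least 50% of the peak was covered in both replicates for 49679 replicated peaks (66.3%), in replicate 1 alone for 18066, in replicate 2 alone for 4941 and in neither for 2266. None of the 10671 pooled peaks left out was covered to that extent in both replicates. Of the replicated peaks, 15756 had no overlap of even 1 bp with a replicate 2 peak, and 5222 had none with a replicate 1 peak. A replicated peak was therefore not always called in both replicates.

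Peaks at promoters had higher signal values than other peaks, and introns held the largest number. Of 74947 replicated peaks on the main chromosomes, 20031 (26.7%, Wilson 95% interval 26.4 to 27) overlapped the 1 kb on either side of the transcription start of a protein-coding gene, and these peaks made up 36.2% of the covered bases. Introns held 43.0%, intergenic regions 27.2%, untranslated regions 1.60% and other exons 1.51%. The median signal value was 7.29 at promoters and 4.14 elsewhere. The promoter share was 25.1% ± 2.93 (SD, n = 2) over the replicates' own lists. At least 1 replicated promoter peak was found at 12137 of 21938 protein-coding genes (55.3%), and 11648 genes had a promoter peak in both replicates' lists.

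Promoters of genes that heart muscle cells use were nearly all marked. A replicated promoter peak lay at 23 of 24 cardiac transcription factor genes, 24 of 25 sarcomere genes, 23 of 24 genes of calcium handling and ion channels, and 24 of 24 genes of fatty acid oxidation and mitochondrial metabolism. Among the transcription factors, Mef2a had signal values of 40.5 in replicate 1 and 35.2 in replicate 2, and Mef2d 39.1 and 34.3. The Gata4 values of 26.1 and 26.7 came from different promoter peaks in the replicates. Gata6 had 23.8 and 27.3. The exception was Isl1, a regulator of early cardiac progenitors, with no promoter peak in either replicate. In the sarcomere list, Myom1, which encodes the M-band protein myomesin, had 45.1 and 31.6, Tnni1, the slow skeletal troponin I used by the fetal heart, 39.7 and 29.8, and Ttn, which encodes titin, 36.6 and 28.6. Obscn, which encodes obscurin, had none. Among calcium and channel genes, the kinase gene Camk2d had 43.8 and 37.1, the sodium-calcium exchanger gene Slc8a1 39.3 and 21.8, and Atp2a2, which encodes the calcium pump of the sarcoplasmic reticulum, 31.3 and 27.2. Of the metabolic genes, the acyl-CoA dehydrogenase gene Acadl had 44.7 and 38.2 and the receptor gene Ppara 31.8 and 25.7. The Fisher exact tests, two-sided and adjusted over the 19 lists, gave p = 4.2e-05 for each of the first 3 lists and p = 1.5e-05 for the metabolic list, against 55.3% of the other coding genes. Against genes of like promoter CpG content, the excess was 25 instead of 40.6 percentage points for transcription factors and 61.4 instead of 40.7 for sarcomere genes.

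For natriuretic peptides and other secreted factors of heart muscle cells, no excess of marked promoters passed the test. Of this list, 6 of 10 members had a replicated promoter peak (Fisher's exact test, adjusted p = 1), an excess of 4.68 percentage points. With the peaks of either replicate alone 7 of 10 had one, an excess of 12.9 points in replicate 1 (exact test, adjusted p = 0.531) and 16.1 in replicate 2 (0.379). Nppb, which encodes brain natriuretic peptide, had signal values of 16.4 and 7.77, while Nppa, which encodes atrial natriuretic peptide, had 4.39 and 3.68, values that came from different promoter peaks in the replicates. Vegfa, a vascular growth factor gene, had 11.9 and 13.4. Fgf16 and Mstn, which encodes myostatin, had no promoter peak in either replicate.

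Cell cycle genes were marked at 23 of 24 promoters (Fisher's exact test, adjusted p = 4.2e-05), with Ccnd3, a cyclin D gene, at 28.6 and 15.8 and Cdk2, a cyclin-dependent kinase gene, at 25.1 and 22.5. Bub1, a gene of the spindle checkpoint, had no promoter peak in either replicate. Against genes of like promoter CpG content, the list no longer passed (permutation test, adjusted p = 0.0871). All 20 housekeeping genes had a replicated promoter peak (Fisher's exact test, adjusted p = 4.2e-05), and Actb, which encodes cytoplasmic actin, had signal values of 58.1 and 43.3. The excess of housekeeping genes was 44.7 percentage points, and 20.0 against genes of like CpG content.

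Genes of the vessels, the epicardium and the vessel wall were marked in most cases. Over the marked members, the median signal value was 8.86 in replicate 1 and 7.26 in replicate 2 for endothelial, 6.85 and 6.30 for epicardial and 6.25 and 5.35 for smooth muscle genes. Of endothelial and endocardial genes, 22 of 24 had a replicated promoter peak (exact test, adjusted p = 0.000433), led by the transcription factor gene Fli1 at 14.9 and 13.6 and the endoglin gene Eng at 10.4 and 13.5. Etv2, an early endothelial regulator, and Flt4, a receptor gene of lymphatic endothelium, had none. Of epicardial and fibroblast genes, 17 of 20 had one (exact test, adjusted p = 0.0106), with Vcan, which encodes the matrix protein versican, at 13.8 and 14.9 and the epicardial regulator Tbx18 at 7.60 and 13.3. Aldh1a2, a retinoic acid synthesis gene, Msln and Upk3b had none. Of smooth muscle and pericyte genes, 13 of 15 had one (exact test, adjusted p = 0.0234), with Smtn, which encodes smoothelin, at 22.6 and 18.6 and Cspg4 at 21.2 and 19.2. Myh11, which encodes smooth muscle myosin heavy chain, and Rgs5 had none. These were Fisher exact tests adjusted over the 19 lists. The smooth muscle list did not pass the exact test with peaks of −log10 p of at least 5 (adjusted p = 0.0839), with the upper 50% of peaks by signal value (0.218) or with replicate 2 peaks alone (0.0840).

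Promoters of genes of other organs, of blood, neural and germ cells and of the Hox clusters were mostly without the mark. A replicated promoter peak lay at 1 of 20 neuronal genes (Fisher's exact test, adjusted p = 2.4e-05), 1 of 16 liver genes (0.00011), 1 of 16 germline and pluripotency genes (0.00011) and 3 of 22 Hox genes (0.000203). The marked members were Elavl4 with signal values of 5.91 and 4.50, Foxa3 with 6.45 and 5.01, Dazl with 3.81 and 4.61, and the anterior genes Hoxa1, Hoxa2 and Hoxb4. Foxa3 has another coding start within 2 kb, and without genes that have such a neighbour 0 of 15 liver genes were marked. Replicate 1 peaks alone marked 6 of 22 Hox genes, a difference of -29.8 instead of -41.7 percentage points (exact test, adjusted p = 0.0139), and 2 of 20 neuronal genes (7.4e-05). Hoxa9, Hoxa11 and Hoxa13, at the other end of the Hoxa cluster, had no promoter peak in either replicate, nor had Alb and Afp, the liver genes of albumin and alpha-fetoprotein. Lung genes were marked in 3 of 15 cases (exact test, adjusted p = 0.0112), among them Hopx at 24.0 and 22.4, which also stood in the cardiac list. Erythroid genes were marked in 4 of 15 cases (exact test, adjusted p = 0.0447), with the transferrin receptor gene Tfrc at 20.1 and 11.6. Macrophage and leukocyte genes (6 of 16, adjusted p = 0.220), skeletal muscle genes (7 of 20, 0.0836) and autonomic neuron and neural crest genes (3 of 12, 0.0505) did not pass the Fisher exact test, adjusted over the 19 lists. Skeletal members with a peak included Tnnt1, the slow skeletal troponin T gene, at 14.7 and 15.3 and Mylpf at 15 and 9.67. For Tnnt1 and for Mylpf, the replicates' values came from different promoter peaks, and Mylpf has another coding start within 2 kb. Acta1, which encodes skeletal actin, had none. Against genes of like CpG content, the difference of liver genes from the others was -25.4 instead of -49.1 percentage points (permutation test, adjusted p = 0.0491). The erythroid and lung lists did not pass against such genes (permutation test, adjusted p = 0.922 and 0.149), where the macrophage list turned to an excess of 6.20 percentage points that did not pass either (0.895). The skeletal muscle difference was -4.22 against such genes instead of -20.3 percentage points (permutation test, adjusted p = 0.922). The erythroid list also did not pass under 4 other settings and the lung list with replicate 1 peaks alone (5 of 15), whereas the macrophage list passed with the upper 50% of peaks (0.0311) and the autonomic list without genes that have another coding start within 2 kb (0.0285). With a promoter window of 2.5 kb the autonomic difference was -15.5 instead of -30.3 percentage points (exact test, adjusted p = 0.404).

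**Figure D2:**
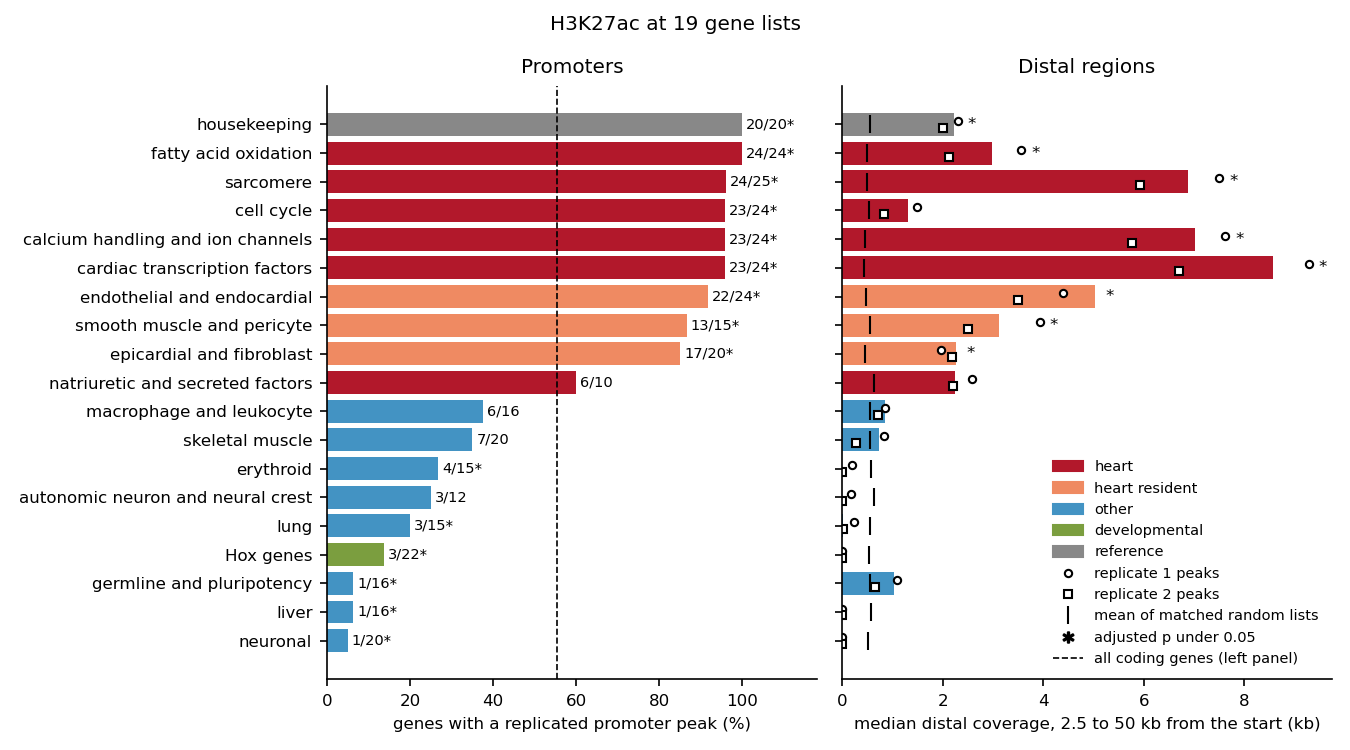
Left, share of each fixed gene list with a replicated promoter peak (x axis, %), with the number of genes marked out of those measured and a dashed line at 55.3% for all coding genes. Right, median distal coverage per list from replicated peaks (bars, kb), from replicate 1 (circles) and from replicate 2 (squares), with ticks for the mean of matched random lists and asterisks for adjusted p under 0.05; cardiac transcription factors reached 8.58 kb, neuronal genes 0.

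Among all coding genes, the strongest promoter peaks lay at Hnrnpl, Gpr19 and Actb. Ranked by the mean of both replicates, the first 10 included Hnrnpl (58.1 and 49.5) and Ptbp1 (54.5 and 46.5), which encode RNA-binding splicing factors, Brd2 (53.8 and 47.4), which encodes a reader of acetylated histones, and Cdk12 (51.8 and 43.5), which encodes a kinase of RNA polymerase II. The others were Gpr19 (56.7 and 46.3), Actb (58.1 and 43.3), Klf7, Efcab2, Dyrk1a and H2-DMa, the last of which shares its peak with Brd2. The median over the 11648 genes with a promoter peak in both replicates was 12.4 and 10.004. Nkx2-5, a homeobox gene of heart formation, had 13.5 and 16.8, and its replicated peak spanned 10.3 kb on chromosome 17 (26835838 to 26846160). Hand2 had 23.6 and 15.5, from different promoter peaks in the replicates. Tbx5 had 14.6 and 9.34, Tnnt2, the cardiac troponin T gene, 26.9 and 24.2, and Actc1, the cardiac actin gene, 21.3 and 14. Myh7, the myosin heavy chain gene that predominates in the fetal ventricle, had 26.5 and 32.1 in a replicated peak of 15.2 kb on chromosome 14 (54981784 to 54996940). Its neighbour Myh6, which predominates in the adult ventricle, had 11.6 and 8.38 in a peak of 7.79 kb (54964110 to 54971895).

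Among the lists, distal acetylation was densest around cardiac genes. From 2.5 to 50 kb on either side of the start, replicated peaks covered a median of 8.58 kb at cardiac transcription factor genes, 7.02 kb at calcium and channel genes, 6.89 kb at sarcomere genes and 5.03 kb at endothelial genes, against 0.417 kb over all coding genes. These medians were 20.0, 15.7, 14 and 10.6 times those of random lists matched on gene density (permutation test, adjusted p = 0.00095 each, from a raw p of 0.0002, the smallest that 10000 random lists can give). Gata4 had 37.4 kb, Nkx2-5 32.1 kb, Atp2a2 27.2 kb, Tnnt2 14.7 kb and Fli1 20.3 kb, whereas Isl1 had 0. Medians were also higher for metabolic genes (2.99 kb, 6.12 times, adjusted p = 0.00228), smooth muscle genes (3.12 kb, 5.58 times, 0.0222), epicardial genes (2.27 kb, 4.95 times, 0.0361) and housekeeping genes (2.23 kb, 4.05 times, 0.0361), by the same permutation test. Each replicate alone gave the cardiac transcription factors 9.28 and 6.71 kb, and the sarcomere genes 7.50 and 5.93 kb. The smooth muscle and epicardial lists did not pass when the window reached 100 kb (permutation test, adjusted p = 0.0931 and 0.256), nor these and the housekeeping list when width was multiplied by signal value (0.0668, 0.117 and 0.0614), nor the epicardial list with replicate 1 peaks alone (0.112). With the 100 kb window the ratios of the other 5 lists were between 2.61 and 9.91, and with width times signal value those of the cardiac transcription factor, sarcomere, calcium and metabolic lists were between 13.8 and 35.4.

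The remaining lists did not pass this test. Natriuretic and secreted factors had a median of 2.26 kb (permutation test, adjusted p = 0.176) and cell cycle genes 1.31 kb (0.220). Germline genes had 1.03 kb (0.544), macrophage genes 0.846 kb (0.549), skeletal muscle genes 0.743 kb (0.593) and lung genes 0.016 kb (0.593). The median was 0 for erythroid, neuronal, autonomic and liver genes (permutation test, adjusted p = 0.549 each) and for Hox genes (0.366). A median of 0 is the lowest possible, and many matched random lists also had it. The raw p of these lists, from 0.212 for Hox to 0.472 for erythroid genes (permutation test), were thus the smallest reachable for lower coverage. With this window the test could not show a lack of distal coverage at them. With replicate 1 peaks alone the median was 0.245 kb for lung, 0.193 kb for erythroid and 0.175 kb for autonomic genes. With replicate 2 peaks alone it was 0.836 kb for cell cycle, 0.648 kb for germline, 0.271 kb for skeletal muscle and 0.009 kb for lung genes, and none of these passed. Hox genes passed, at a ratio of 0, only with the 100 kb window (0.00608), where the autonomic and skeletal muscle lists changed direction without passing (ratios of 1.15 and 0.759, both 0.804).

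The first-ranked distal domains were nearest to Rbpms, Frmd8, Igf2r, Rbm20 and Msi2. Neighbouring distal peaks were joined into 17729 domains, of which 987 lay past the tangent point and held 46.0% of the summed width times signal value. Their median span was 29.6 kb, against 1.19 kb for the others. The first was nearest to Rbpms, which encodes an RNA-binding protein, and spanned 151 kb and 63 peaks on chromosome 8 (33772981 to 33924256), largely within the gene. The fourth was nearest to Rbm20, the gene of a splicing factor that acts on titin, and spanned 184 kb on chromosome 19 (53648055 to 53831568). The fifth lay within Msi2, an RNA-binding protein gene, and was the longest at 323 kb on chromosome 11 (88351437 to 88674051). The second (chromosome 19, 5786622 to 5852849) was nearest to Frmd8 and the third (chromosome 17, 12712717 to 12810698) to Igf2r, a receptor gene. The domains ranked 6 to 15 were nearest to Mical2, Cstad, Zmiz1, Chd2, Ahdc1, Tns1, Lrrc74a, 2310022B05Rik, Hspg2 and Cxxc5. The strongest peaks of the Mical2, Zmiz1 and Tns1 domains were intronic, that of the Lrrc74a domain intergenic. When peaks near long non-coding RNA starts were also left out, Frmd8 fell to rank 53, Igf2r to 34, Cstad to 99 and Chd2 to 87. Of the 987 domains, 94.8% overlapped a top domain made from replicate 1 alone and 77.8% one made from replicate 2 alone.

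**Figure D3:**
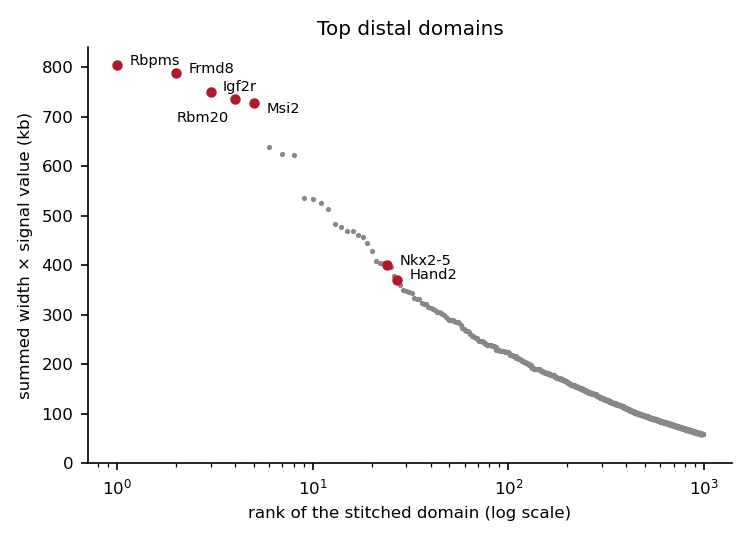
Summed width times signal value (y axis, kb) of the 987 top distal domains by rank (x axis, log scale), each point a domain, with 7 domains named in red by their nearest coding gene. The first 5 lie between 727 and 803, the Nkx2-5 domain at rank 24 at 399 and the Hand2 domain at rank 27 at 371.

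Genes of cardiac transcription factors, calcium handling and the sarcomere were nearest to top domains more often than other genes. Of the cardiac transcription factor genes nearest to any domain, 13 of 21 were nearest to a top domain, among them Gata4, Gata6, Mef2a, Mef2d, Nkx2-5, Hand2 and Hopx (Fisher's exact test, adjusted p = 3.5e-07). Other genes nearest to a domain had a share of 10.5%. For calcium and channel genes the count was 9 of 22 (exact test, adjusted p = 0.00219), including Atp2a2 and Camk2d, and for sarcomere genes 7 of 21 (adjusted p = 0.0290), including Tnni1. The Nkx2-5 domain held 21 peaks over 59.5 kb on chromosome 17 (26835068 to 26894517), and that of Hand2 17 peaks over 58.2 kb on chromosome 8 (57303611 to 57361794). Without peaks near long non-coding RNA starts, the Nkx2-5 domain fell to rank 45 and that of Hand2 to rank 2472. The sarcomere list did not pass with a joining distance of 5 kb (exact test, adjusted p = 0.0760) or with replicate 2 peaks alone (0.0609), and its excess was 70.8 instead of 22.8 percentage points when promoter peaks were included. That of cardiac transcription factors was then 67.2 instead of 51.4, below the sarcomere list.

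For the other lists the excess at top domains did not pass the Fisher exact test. The counts were 4 of 13 metabolic genes (exact test, adjusted p = 0.197, and 0.00274 with promoter peaks included), 4 of 20 endothelial genes (0.524), 2 of 11 smooth muscle genes (0.783), 1 of 16 epicardial genes (1), 1 of 10 cell cycle genes (1) and 1 of 7 natriuretic and secreted factor genes (0.863). Neuronal and lung genes had 1 of 6 each (0.863), skeletal muscle genes 1 of 7 (0.863), germline genes 1 of 3 (0.777) and housekeeping genes 2 of 7 (0.524). The housekeeping excess of 18.0 percentage points was 0.805 with replicate 1 peaks alone and 10.8 with replicate 2 peaks alone. None of the 2 erythroid, 7 macrophage, 4 autonomic, 2 liver and 2 Hox genes nearest to a domain was nearest to a top domain (1 each).

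**Figure D4:**
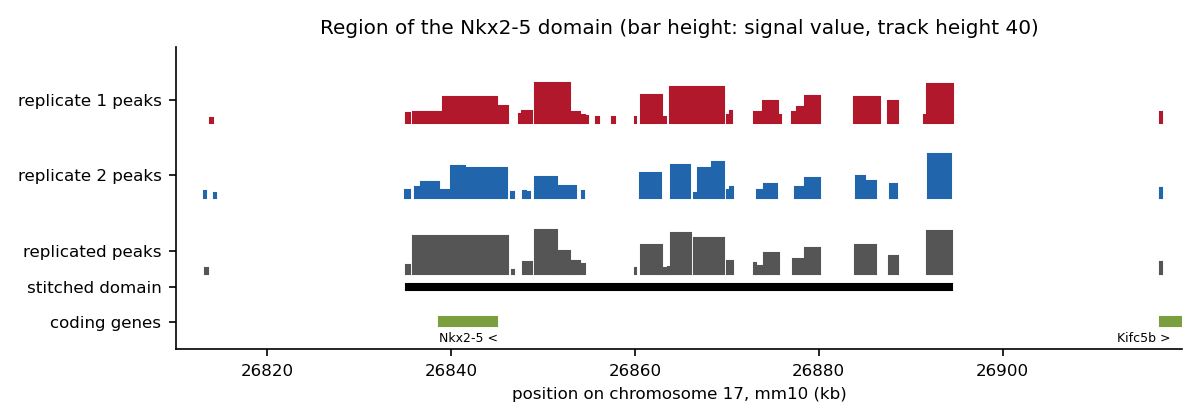
Map of the Nkx2-5 region on chromosome 17 (x axis, kb on mm10), with bars for peaks of replicate 1, replicate 2 and the replicated list whose height is the signal value on a scale of 40 per track, the joined domain in black and coding genes in green with their strand. The domain runs from 26835068 to 26894517, and its peaks upstream of Nkx2-5 recur in both replicates.

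Distal peaks held several binding motifs of cardiac and of general transcription factors more often than matched genomic windows. In 49804 windows of 500 bp centred on distal summits, the MEF2 consensus YTAWWWWTAR occurred in 9.74%, against 5.52% of windows matched on GC content (ratio 1.77, Fisher's exact test, adjusted p = 1.6e-139). GATA (AGATAAG) occurred in 8.15% against 5.76% (1.41, 3.7e-49), TEAD (RGAATGY) in 31.2% against 25% (1.25, 4.6e-105) and NKX2 (TYAAGTG) in 13.5% against 11.4% (1.19, 1.6e-23). The general motifs AP-1 (TGASTCA, 10.9% against 8.36%, 2.1e-40), SOX10-like (ACAAWGG, 18.8% against 16.8%, 4.4e-16) and ETS (ACCGGAAGT, 0.211% against 0.129%, 0.00298) were also more frequent. SRF (CCWWWWWWGG) was found in 2.72% against 2.71% (exact test, adjusted p = 0.938). Of the motifs chosen for other organs, CRX (TAATCC) was less frequent (14.9% against 16.2%, 3.5e-08), and HNF4 (0.215), HNF1 (0.501) and RFX (0.501) did not pass. These were Fisher exact tests, two-sided and adjusted over the 12 motifs. In windows of 200 bp the MEF2 and ETS ratios fell to 0.946 (exact test, adjusted p = 0.404) and 0.828 (0.750) and that of SRF to 0.795 (0.000754). Against the peaks' own flanks the MEF2 ratio was 1.12 (exact test, adjusted p = 6.1e-11). There the ratios were 1.22 for GATA, 1.20 for TEAD, 1.05 for NKX2, 1.22 for AP-1, 1.11 for SOX10-like and 1.67 for ETS.

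**Figure D5:**
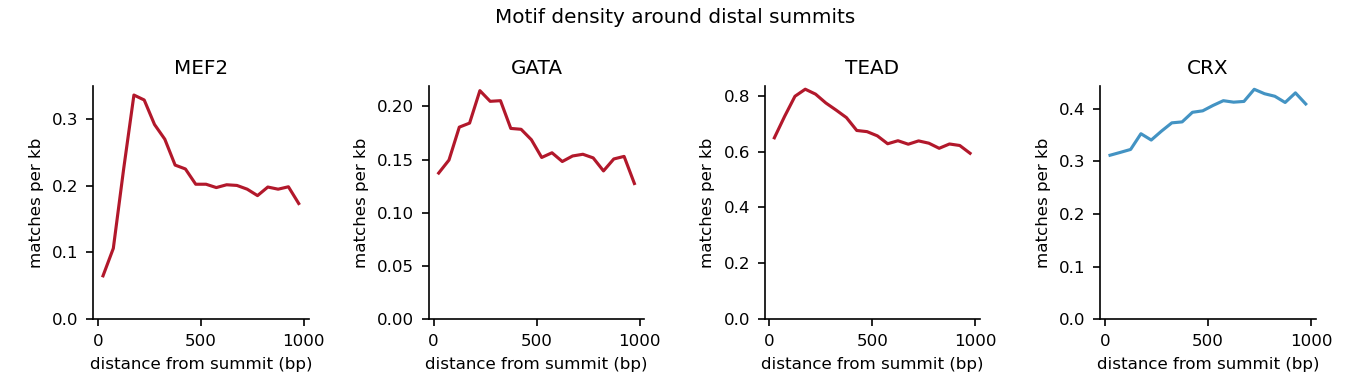
Matches per kb (y axis, a separate scale per panel from 0) of the MEF2, GATA, TEAD and CRX consensus sequences by distance from the summit of distal replicated peaks (x axis, bp, both sides together, bins of 50 bp). The MEF2 density was 0.0855 within 100 bp of the summit, 0.296 from 100 to 250 bp and 0.190 from 750 to 1000 bp.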

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

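Of the tests in this part, those of summits on nucleosomes and of the lung genes on their own were chosen after the results were seen. On unplaced or unlocalised sequences there were 5 replicated peaks, with signal values from 2.53 to 35.9. They are listed because they were left out of the comparisons between the replicates' lists and of those with genes and motifs, and exceed the limit of 3 that a count of 0 allows.

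About 50% of replicate 1 peaks were less than 50% covered by replicate 2 peaks, while 59.5% had an overlap of at least 1 bp. With 1 group, explanations could be examined only within these 2 libraries. Lower detection power in replicate 2 is a candidate explanation. The 50059 unshared peaks of replicate 1 had a median −log10 p of 5.15, below the lower quartile of 7.21 in shared peaks, and 13.9% against 31.8% lay at promoters. Unshared replicate 2 peaks were also weaker, with a median of 3.66 against 7.31 in shared ones. Weakness of unshared peaks thus does not tell which library is the cause. At the 55771 pooled peaks matched in both replicates, median −log10 p was 12.8 in replicate 1 and 7.31 in replicate 2. The median signal values there were 5.64 and 4.91. Lower −log10 p in replicate 2 at the same regions goes with lower detection power in that library. Depth is unknown, so the explanation stays open. Other cell types in the tissue of replicate 1 met the criterion set in advance, because the lung list had 57 of 89 nearby peaks unshared (Fisher's exact test, odds ratio 1.85, adjusted p = 0.0391), and the 7 lists of other organs together gave an odds ratio of 1.28 (95% interval 1.03 to 1.59). At equal peak strength the odds ratio over these lists was 1.06 (0.821 to 1.38), inside the bounds set in advance against this explanation. Peaks from a small share of other cells would themselves be weak, so matching on strength can remove their effect. Other cell types therefore stay open. For the lung list alone the odds ratio at equal strength was 1.57 (0.888 to 2.77). Without Hopx, also a cardiac gene, 48 of the 89 lung peaks were left, and the lung odds ratio at unequal strength was 2.07 (1.14 to 3.78). Single peaks were the units of these odds ratios, and peaks near the same gene are not independent. The p-value and intervals are therefore likely too narrow, and a part played by lung tissue also stays open.

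In the lists of other organs and of blood, neural and germ cells, 26 of 130 promoters were marked. The marked genes included 4 of 15 erythroid, 6 of 16 macrophage and 3 of 12 autonomic genes. Whether such cells within the heart tissue carried the mark was not tested. CpG-rich promoters could carry the mark in any tissue, but the median ratio of observed to expected CpG was 0.355 with a peak and 0.297 without, a difference of 0.0578 that a permutation test did not separate from chance (p = 0.529). A neighbouring gene's promoter was within 2 kb of 7 of the 26 marked members (26.9%) and 4 of the 104 others (3.85%). The 7 were Abca3, Actn3, Cd68, Foxa3, Gata3, Mpz and Mylpf. The share of 26.9% lies between the bounds set in advance, so a neighbour stays open as an explanation for those 7, and CpG content stays open for all 26, of which Hopx is also a cardiac gene.

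MEF2 motifs were less dense within 100 bp of distal summits than 100 to 250 bp away, at a ratio of 0.288, and no biological explanation could be set against a group. Base composition at the summit argues in the same direction, since GC content was 50.2% at the summit and 45.1% far from it, but 20 shuffled MEF2 words gave ratios of 0.350 to 0.4996, so composition as measured by these words leaves part of the dip unaccounted for. Summits on acetylated nucleosomes beside the bound site may add to it: the GATA ratio of 0.742 and that of MEF2 lay below all 20 of their shuffled words, while 1 word was at or below TEAD and 8 at or below NKX2. All 12 motifs had ratios under 1, so a first form of this test told nothing apart and was tightened. The nucleosome explanation stays open, because the motifs did not behave alike and nucleosome positions were not analysed here.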

How the results depend on the processing

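Leaving out genes with a neighbouring coding start and leaving out peaks near long non-coding starts were chosen after seeing the data; the other alternatives were planned. Of 367 alternatives, 304 kept direction and side of the threshold or stayed within the spread, 19 lost the call, 4 gained one, 27 changed direction and 13 moved. The 11 promoter lists, 5 distal lists, 2 domain lists and 6 motifs that passed under all alternatives run include the cardiac transcription factor and calcium lists in each case, and GATA, TEAD and NKX2. The number of top domains ran from 833 to 1370. Depth is unknown, and weak peaks were shared least. No paired analysis was possible because there is 1 group. For each change given here the cause was not tested.

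With any overlap of 1 bp, 59.5% of replicate 1 and 84.7% of replicate 2 peaks were shared, with reciprocal overlap of 50%, 41.5% and 54.3%, at −log10 p of at least 5, 50.4% and 88.7%, and with equal numbers of peaks, 61% and 73.9%. The correlation was 0.805 with −log10 p in place of the signal value. At −log10 p of at least 5, 97.3% of pooled peaks were in the replicated list and 30.4% of replicated peaks lay at promoters, and a window of 2.5 kb gave 33.5%. Each replicate alone gave 23.0% to 27.2%.

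Promoter lists are given as differences from other genes in percentage points. Against genes of like CpG content, the values were 15.2 for cell cycle, -5.91 for erythroid, -25.4 for liver, -19.9 for lung, -4.22 for skeletal muscle and 6.20 for macrophage genes. At −log10 p of at least 5 they were 26.4 for smooth muscle and -26.9 for erythroid genes. With the upper 50% by signal value they were 17.1 for smooth muscle, -23.0 for erythroid and -30.9 for macrophage genes. Without genes that have a neighbouring start they were -23.0 for erythroid and -39.6 for autonomic genes. Each replicate alone gave 26.1 to 29.6 for smooth muscle, -30.4 to -27.3 for erythroid, -40.7 to -23.8 for lung, -13.3 to -10.2 for macrophage and 12.9 to 16.1 for natriuretic and secreted factor genes.

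Distal lists are given as ratios to matched random lists. With a window of 2.5 to 100 kb they were 2.14 for epicardial, 2.81 for smooth muscle, 1.15 for autonomic, 0.759 for skeletal muscle and 0 for Hox genes. With width times signal value they were 4.54 for epicardial, 5.87 for smooth muscle and 5.08 for housekeeping genes, so these calls ended with ratios near or above the main ones. Each replicate alone gave 3.45 to 6.53 for epicardial and 0.656 to 1.24 for skeletal muscle genes.

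Lists at top domains are given as differences in percentage points, and most rest on fewer than 10 genes. With a joining distance of 5 kb they were 19 for sarcomere, 0.373 for cell cycle, -1.30 for smooth muscle, 4.66 for macrophage and -9.64 for skeletal muscle genes. With promoters included they were 31.0 for metabolic, -11.2 for neuronal and -11.2 for germline genes. With long non-coding starts left out they were 0.168 for cell cycle, -0.742 for smooth muscle and -9.84 for neuronal genes. Each replicate alone gave 19.4 to 24.7 for sarcomere, 0.805 to 0.810 for cell cycle, -9.19 to 14.7 for germline, 0.810 to 2.20 for macrophage, -10.3 to -9.20 for neuronal, -10.3 to 7.48 for skeletal muscle, -9.21 to 12.8 for smooth muscle, 0.805 to 10.8 for housekeeping and 5.10 to 11.9 for natriuretic and secreted factor genes.

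In windows of 200 bp the motif ratios were 0.946 for MEF2, 0.795 for SRF, 0.828 for ETS and 0.939 for RFX, and against flanks 2 kb away the HNF1 ratio was 0.941.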

Other observations

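The splicing, atrial and ventricular lists, the count of non-coding starts and the tests of promoter signal by cell type, pooled and by list, and of splicing regulators were chosen after the results were seen. The list of 25 genes of RNA-binding splicing regulators was prompted by members already seen (Hnrnpl, Msi2, Ptbp1, Qk, Rbm20 and Rbpms), so a test of all 25 carries no weight and only that of the other 19 is given. Of these, 18 had a replicated promoter peak (Fisher's exact test, p = 0.000276, adjusted p = 0.000552), Esrp1, an epithelial splicing factor gene, being the exception. Promoter CpG content was not matched in this test. Housekeeping genes were marked at 20 of 20 and cell cycle genes at 23 of 24 promoters, so such marking was not particular to splicing regulators. The median distal coverage of the 19 splicing regulators, 1.39 kb, did not pass (permutation test, adjusted p = 0.130). Adjustment was over 4 lists, the full splicing, atrial and ventricular lists included, all 4 of which were tested. Mbnl1 had signal values of 37.5 and 34.5, Rbm24, a muscle splicing factor gene, 31.3 and 25.9, and Rbfox2 28.9 and 30.1. Ventricular genes were marked at 8 of 8 promoters with a median of 10.1 kb of distal coverage, and 3 of 7 (Irx4, Lbh and Myl2) were nearest to top domains. Atrial genes were marked at 10 of 11 promoters, all but Sln, with 2.35 kb, and 1 of 9, Myl7, was nearest to a top domain. Most members of both lists had been seen in other lists before these were written, so their tests carry no weight and are not given. Whether the ventricular and atrial lists differ was not tested. All genes in this part were chosen after their values were seen or belong to these lists.

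Several top domains held starts of long non-coding RNAs. Such a start lay in 285 of 987 top domains (28.9%) and in 995 of 16742 others (5.94%), which are shorter, and the difference was not tested at equal length. The domain nearest to Frmd8 held Malat1 and Neat1, which encode abundant nuclear RNAs, and that nearest to Igf2r held Airn, the antisense RNA of the imprinted Igf2r locus. The domain nearest to Il17b, at rank 19 on chromosome 18 (61627920 to 61678281), held Carmn and Bvht, RNA genes of muscle and heart lineages. The Hand2 domain held Hand2os1. On the X chromosome, replicated peaks were sparser than on autosomes, at 8.01 against 29.9 per Mb and 1.45 against 3.54 per coding gene.

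A candidate explanation for the splicing regulators is that such genes lie beside top domains more often than other genes, and 9 of 18 members did. Because several of them had prompted the list, a separate test took only members not already seen. Of these, 5 of 13 (Mbnl2, Rbfox2, Rbm24, Rbm38 and Rbpms2) were nearest to a top domain, 38.5% against 10.6% of other genes, a difference of 27.9 percentage points (Fisher's exact test, p = 0.00835, adjusted p = 0.0167). The list was written by hand with the first domains in view, so this remains a hypothesis.

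Promoter signal may follow the share of the tissue made of cells that use a gene. Among genes with a promoter peak in both replicates, 100 members of the cardiomyocyte lists had a median signal value of 18.0 and 51 endothelial, epicardial and smooth muscle members 7.11, a difference of 10.9 (permutation test, p = 1e-05, the smallest that 100000 permutations can give). The medians were 19.7 and 7.60 in replicate 1 and 16.6 and 6.81 in replicate 2. Housekeeping genes, used by all cell types, had medians of 17.9 in replicate 1 and 13.7 in replicate 2. These lay below the cardiomyocyte members and above the others, an order that cell share alone would not give. The housekeeping difference was not tested. Taken singly, 4 of the 5 cardiomyocyte lists lay above the other cell types (permutation test, adjusted p = 1.25e-05 each). The natriuretic and secreted factors did not, with a median of 4.99 over 6 genes and a difference of -2.13 (permutation test, adjusted p = 0.171). For this list the direction was the other way without passing, so the explanation has no support there and is not excluded. List medians had been seen before the pooled and the single tests were chosen. Their p-values therefore describe a difference already seen and add no support to the explanation. Promoter CpG content was similar, with medians of 0.429 and 0.448. Neither cell shares nor expression level per cell was analysed here, and either could contribute to a higher signal at the cardiomyocyte members.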
